A study of Mus musculus with 2 samples.

How the data were processed

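RNA of SN4741 cells, an immortalized dopaminergic neuronal line of the mouse grown at 33 C per the labels, was measured on 2 single-colour Illumina arrays. The control group had 1 array (0 h) and the group overexpressing Oxi-beta had 1 array (12 h), each with RNA pooled from 3 samples. Per the labels' protocols, total RNA was extracted with Trizol, purified on columns and amplified to biotinylated cRNA. How Oxi-beta was introduced, and whether control cells received an empty construct, is not given in the sources used here. The submitters' processing notes name BeadStudio without a version.

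The deposited non-normalized table holds, per the file headers, a signal intensity for each of 24613 probes on each array. It also holds a detection p-value for each probe and array, per the file headers. The signal columns are named as control and test, and the column named test was taken as the overexpression array, the only sample that was not the control. This was checked against the authors' value table, whose columns are tied to the samples. The authors' value table holds deposited log2 signals of 11090 probes, exactly those with a detection p-value under 0.05 on at least 1 array. Its columns hold the same set of values in different order (largest difference between the sorted columns 0, median 9.19 in each), as quantile normalization gives, and each correlated across probes with the log2 signal of its own array at r = 0.99998, against 0.99623 between the control values and the overexpression signals. The log2 scale and quantile step are read from these values, and no label states them. Values of single genes were not centred.

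Probes were named through the platform's annotation table for the probes of the authors' table, so a probe outside it is unnamed here. Of the 11090 probes, 9762 had 1 gene symbol, 1328 had none and 0 had several. Entrez identifiers of 9757 probes were found among the genes of mouse RefSeq (assembly GRCm38.p6), and 0 symbols needed updating. No build is named for the arrays, so no coordinates are given. The named probes stood for 7939 genes, 1478 of them with several probes. Another 998 detected probes had no symbol and stayed out of the gene counts. A symbol in a gene list that is no longer current was matched through RefSeq synonyms. A first version of this matching accepted ambiguous synonyms and put unrelated genes into several lists. It was corrected after list values had been seen, and the correction moved the NF-kappaB list outside and the pan-neuronal list inside the central 95% of random lists.

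Signals were corrected for background with limma 3.58.1 in R 4.3.3 (nec, which fits a normal and exponential model from the detection p-values, offset 16), quantile-normalized and put on the log2 scale. Quantile normalization assumes that the distribution of levels is the same on both arrays. The offset and the background affect differences of dim genes. The median signal was 88.2 on each array over only those undetected probes with the highest detection p-values. A probe was detected at a detection p-value under 0.01. The lowest detected signal was 201 on the control array and 196 on the overexpression array, and the median signal of detected probes was 915 and 856. A gene was represented by its named probe of highest mean signal and counted when that probe was detected on at least 1 array. Of 6702 such genes, 107 were detected on the overexpression array only and 125 on the control array only. For these, the fold is a bound and is written as "at least". The bright array's normalized value was set against the higher of the lowest value among detected probes and the probe's own value on the dim array. It is a bound on the background-corrected scale. Subtracting background widens ratios, so a bound can exceed the ratio of the deposited signals, and it changes with the background model. Differences are overexpression minus control. Where a gene had several probes detected on both arrays (999 genes), the root mean square of the SD of their log2 differences was 0.149, which measures disagreement between probes and not between samples.

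The design, the alternatives, the 30 gene lists and the rule for named genes were fixed before the data were examined. The main result was the number of genes at least 2-fold higher or lower. Each list with 5 or more detected members had its median log2 difference placed as a percentile among medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This describes the 2 arrays and is no test of the conditions. Of the mitochondrial-genome list, 0 genes had a named probe, so RNA quality was not judged that way. Reactome pathways of the fgsea 1.28.0 example set were treated in the same way as an exploratory step, with 10 to 200 detected members each. Named genes were chosen by rule. Among genes detected on both arrays these were the 12 with the highest and the 12 with the lowest difference, and among genes detected on 1 array the 3 with the largest bound in each direction. From each list described, up to 2 members with the highest and up to 2 with the lowest difference among those detected on both arrays could be named, and all detected dopaminergic markers were named. Clone and locus labels were passed over. Genes outside the rule are said to have been chosen after their values were seen. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

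The steps were tested on simulated data. The control array was copied, array noise of the size seen between the real arrays was added, and 200 of 6711 genes were changed by known folds. Of the 50 genes made 4-fold higher, 100% came out at 2-fold or more, and of the 50 made 2-fold higher, 100% came out at 1.5-fold or more and 46% at 2-fold or more. Of the 50 made 2-fold lower, 96% came out at 1.5-fold or more lower. Of the unchanged genes, 0.34% passed 1.5-fold and 0.031% passed 2-fold. The noise was normal, with a spread set by the median absolute deviation of the real log2 ratios, so rare large differences were not simulated. The shares of unchanged genes that pass could therefore be higher on real arrays. The changed genes were drawn from those with 1 named probe that was detected on the control array. The recovery rates therefore do not cover genes detected on the overexpression array only. Of 100 simulated lists of 15 unchanged genes, 2 lay outside the central 95% of random lists, and 100 of 100 lists shifted by 0.2 did. The 0.2 was added to each member after normalization, and smaller shifts were not simulated.

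The alternatives were the authors' own values, no background correction with signals floored at the lowest detected signal, an offset of 50, median centring or cyclic loess in place of quantile normalization, detection at 0.05, detection on both arrays, no filter, the mean over a gene's detected probes, fold thresholds of 1.5 and 3, random lists without matching and lists limited to members detected on both arrays. Named probes all had a detection p-value under 0.05 on at least 1 array, so no filter kept the same genes as detection at 0.05. Counts, list medians and list percentiles with genes detected on 1 array at their bounds were added after the data were seen. Replicates could not be left out in turn, because each group had 1 array. Batches could not be examined for the same reason.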

Results

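Expression was measured on 2 Illumina mouse bead arrays of SN4741 cells, an immortalized dopaminergic neuronal line of the mouse. The control array carried RNA of cells at 0 h, and the overexpression array carried RNA of cells that had overexpressed Oxi-beta for 12 h. Each array held a pool of 3 samples, so each group had 1 array and no replicate array. No test across samples was possible, no p-value is given for any difference, and the number of arrays limits the precision of every value. Oxi-beta is known in the literature as a name of Tnfaip8l1, a relative of TNF-alpha-induced protein 8, although the labels give only the name Oxi-beta. Among the probes with a gene symbol, 0 were named Tnfaip8l1, so the level of the introduced gene had no direct reading. Only probes with a detection p-value under 0.05 on at least 1 array could carry a symbol. A Tnfaip8l1 probe undetected on both arrays therefore cannot be told apart from a missing one. The overexpression itself was not checked here. Of 24613 probes per array, 8814 (35.8%) were detected on the control array and 8799 (35.7%) on the overexpression array, with median signals of 127 and 128. Named probes represented 6702 genes detected on at least 1 array, 6470 of them detected on both. Across these 6702 genes, which are not independent replicates, the normalized log2 signals of the arrays correlated with r = 0.994. The central 95% of the log2 differences ran from -0.34 to 0.33.

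The comparison addressed which transcripts differed in level after Oxi-beta overexpression. The differences of 2-fold or more lay almost entirely on the higher side, and many belonged to genes known to be switched on by type I interferon. Irf9, the DNA-binding subunit of the interferon-activated factor ISGF3, was 4.96-fold higher on the overexpression array, and Bst2, which tethers budding virus to the cell surface, was 3.28-fold higher. Tnfaip8, the founding member of the protein family of Tnfaip8l1, was 14.0-fold higher. Transcripts of Fbxw5, a substrate receptor of ubiquitin ligases that Tnfaip8l1 has been reported to bind, and of Pop4, a subunit of the RNA-processing enzymes RNase P and RNase MRP, were not well above background on the control array. On the background-corrected scale they were at least 26.1-fold and at least 29.0-fold higher on the overexpression array, while the ratios of their deposited signals were 26.8 and 16.6 and the lowest folds among the alternatives were 14.8 and 16.4. Each fold written as at least is a bound on the background-corrected scale, which moves with the background model. In all, 19 genes were at least 2-fold higher and 1 gene was at least 2-fold lower. Of the 19, 10 belonged to the interferon list, 9 did not, and 14 were detected on the overexpression array only. With those 14 genes taken at their bounds, 14 genes stayed at 2-fold or more higher and 0 lower. Among genes detected on both arrays the counts were 5 higher (Tnfaip8, Irf9, Bst2, Parp12 and Ifi35) and 0 lower. With uncorrected signals floored at the lowest detected signal the counts were 8 higher and 0 lower, and 13 of the 19 genes had a ratio of deposited signals of 2 or more.

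**Figure D1:**
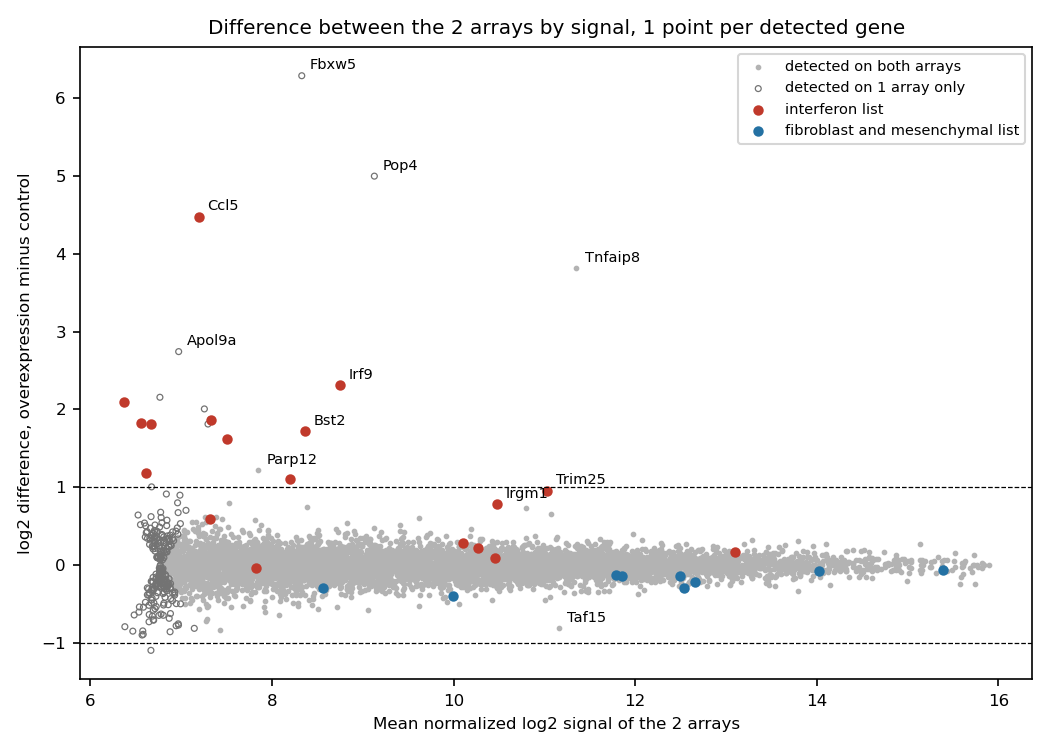
Log2 difference (overexpression minus control) against the mean normalized log2 signal, with 1 point for each of the 6702 detected genes, open circles for genes detected on 1 array only, colours for the interferon and the fibroblast and mesenchymal lists, and dashed lines at 2-fold. Tnfaip8 (3.81) and the interferon genes Irf9 (2.31) and Bst2 (1.72) stand above the band of genes detected on both arrays, and fitted differences of open circles such as Fbxw5 (6.29) are not bounds.

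The interferon list held 45 genes induced by type I interferon or cytosolic nucleic acid, of which 18 were detected on at least 1 array. Of these 18, 17 had a positive difference, 13 were at least 1.5-fold higher, and H2-D1, a class I histocompatibility gene, was the exception at -0.035. Their median log2 difference was 1.14, or 2.21-fold, above the median of each of 10000 random lists matched on expression. Members detected on both arrays had a median of 0.59, again above all random lists. Trim25, a ubiquitin ligase that acts on the RNA sensor RIG-I, was 1.94-fold higher at signals of 1642 and 2906. Ifi35 was 2.14-fold higher, and Irgm1, a GTPase of innate immunity, was 1.72-fold higher. Ccl5, a chemokine that attracts T cells, was not well above background on the control array and was at least 6.34-fold higher on the overexpression array, with 3.94-fold as the lowest value among the alternatives. Differences were smaller for B2m, the light chain of class I histocompatibility molecules (0.17), Irf1 (0.29) and Ifit2 (0.084). B2m and Irf1 were named after their values were seen. Among genes outside the list that are also known targets of interferon, Parp12, an ADP-ribosyltransferase, was 2.33-fold higher and the RNA-editing enzyme Adar was 1.74-fold higher. The entry-blocking membrane protein Ifitm3 was 1.67-fold higher, and Eif2ak2, the kinase PKR that responds to double-stranded RNA, was 1.66-fold higher. Of the list's 18 detected members, 7 had only a bound, and with bounds in place of fitted values the median was 0.74. With the authors' values the median was 0.88, and with uncorrected signals floored at the lowest detected signal it was 0.46. No array was labelled as cells given an empty construct, and whether the control cells received one is not given in the sources used here.

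Several transcripts outside the interferon list were also higher. The signals of Tnfaip8 were 814 and 9628 on the control and overexpression arrays, those of Fbxw5 were 106 and 2837, and those of Pop4 were 190.0 and 3151. Each of these 3 genes was represented by 1 named probe, so no further probe of the same gene could be set beside it. Ddx6, an RNA helicase of processing bodies, was 1.58-fold higher by its detected probe, and Rgs16, a regulator of G protein signalling, was 1.54-fold higher. Rgs16 lay near background, at signals of 215 and 274 with a deposited ratio of 1.27, and its lowest fold among the alternatives was 1.31. The remaining members of the 9 genes outside the interferon list were chosen after their values were seen. That list does not hold every known target of interferon, Parp12 being outside it. A place outside the list therefore does not make a gene unrelated to interferon. With their bounds, Apol9a was at least 2.98-fold higher, Ifi27 at least 2.81-fold, Dtx3l at least 2.70-fold, Apol9b at least 2.11-fold and Zfp770 at least 1.33-fold. The ratios of deposited signals, in which background is left, were 3.09 for Apol9a, 2.31 for Ifi27, 2.14 for Dtx3l, 2.30 for Apol9b and 1.43 for Zfp770.

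**Figure D2:**
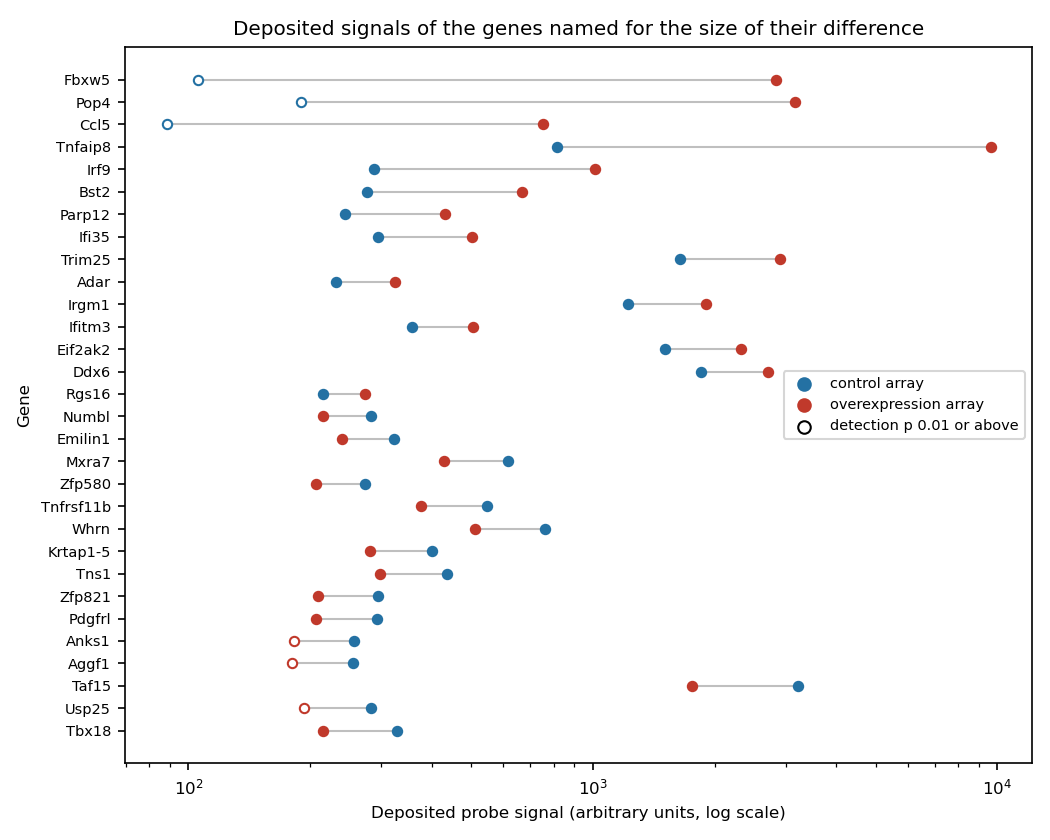
Deposited probe signals before any normalization, in arbitrary units on a log axis, for the genes named for the size of their difference, with blue for the control array, red for the overexpression array and open circles where the detection p-value was 0.01 or above. Tnfaip8 lay at 814 and 9628 and Taf15 at 3216 and 1756 on the control and overexpression arrays, and open circles mark Fbxw5, Pop4 and Ccl5 on the control array.

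Among named genes, those with lower transcript levels showed smaller differences and lay mostly near background. Taf15, an RNA-binding protein, was 1.76-fold lower on the overexpression array, at signals of 3216 and 1756. Tbx18, a T-box transcription factor of mesenchymal lineages, was 1.79-fold lower, and Pdgfrl, a protein related to the PDGF receptors, was 1.65-fold lower. Tns1, which links integrin adhesions to actin, was 1.56-fold lower. Emilin1, a glycoprotein of elastic fibres, was 1.46-fold lower, and Tnfrsf11b, the secreted decoy receptor osteoprotegerin, had a log2 difference of -0.57. Log2 differences were -0.70 for Zfp821, -0.60 for Krtap1-5, -0.58 for Whrn, a scaffold protein of hair cells, -0.57 for Zfp580, -0.55 for Mxra7 and -0.55 for Numbl, a relative of the fate determinant Numb. Among genes not well above background on the overexpression array, Usp25, a deubiquitinating enzyme, was at least 1.71-fold lower, Anks1 at least 1.49-fold and Aggf1 at least 1.47-fold. Their deposited signals on the overexpression array were 0.685, 0.710 and 0.708 of those on the control array. The only gene at 2-fold or more lower was Col8a2, a collagen chain detected on the control array only, and its bound was 1.36-fold (named after its value was seen). At 1.5-fold, 39 genes were higher and 29 lower, and 23 of the 29 were detected on the control array only. With bounds the counts at 1.5-fold were 31 and 7, and among genes detected on both arrays they were 16 and 6. In the simulated data, 0.34% of 6511 unchanged genes passed 1.5-fold in either direction, with noise that left out rare large differences. Of the 29 lower genes, Taf15 was the only one with a control signal above 915, the median of probes detected on that array.

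Fibroblast and mesenchymal genes were lower as a group, each by a small amount. All 9 detected members of this list had negative differences, and the median was -0.14, at percentile 0.05 of matched random lists. Pdgfrb, the receptor for PDGF-BB, had a log2 difference of -0.40, and Sparc, a secreted matrix protein, had -0.30. The intermediate filament gene Vim was at -0.066 and S100a4 at -0.075. No member reached 1.5-fold, and the 3 probes of Fn1, the fibronectin gene, went from -0.13 to 0.094 (named after its values were seen). No untreated array labelled 12 h was among the samples, so any difference in hours in culture could not be separated from overexpression. Targets of TGF-beta, BMP and YAP had a median of -0.068 over 18 genes at percentile 2.71, just inside the central 95% of random lists, and at percentile 2.45, outside it, when genes detected on 1 array were set at their bounds. All 18 genes were detected on both arrays, so this crossing came from the random lists alone. Within that list Tgfb3, a TGF-beta ligand, was at -0.39 and the matrix protein gene Tgfbi at -0.38, while Id1, a target of BMP signalling, was at 0.23 and Amotl2 at 0.14.

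Nucleolar and inflammatory genes lay slightly higher on the overexpression array. The list of nucleolar and ribosome assembly factors had a median of 0.087 over 21 genes, at percentile 99.87, with 17 members positive and 4 negative. Nolc1 (0.28) and the nucleolin gene Ncl (0.27) were its highest members, and Noc2l (-0.11) and Nop58 (-0.053) its lowest. Under median centring, which lowered the median of all genes to -0.10, this list's median was -0.002, or 0.098 relative to all genes. The list of NF-kappaB targets and inflammatory mediators had a median of 0.13 over 11 genes, at percentile 99.56. Its highest members were the neutrophil chemokine gene Cxcl1 (0.46) and the NF-kappaB subunit gene Relb (0.25), and its lowest were Ptgs2, which encodes an inducible enzyme of prostaglandin synthesis (-0.071), and the NF-kappaB inhibitor gene Nfkbia (-0.055). Control signals of Cxcl1 (238) and Relb (256) were near the lowest detected signal of 201. No gene of either list reached 1.5-fold. Of 25 lists with a percentile, 4 lay outside the central 95% of random lists, namely the interferon, fibroblast and mesenchymal, ribosome assembly and NF-kappaB lists, where 1.2 are expected by chance.

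**Figure D3:**
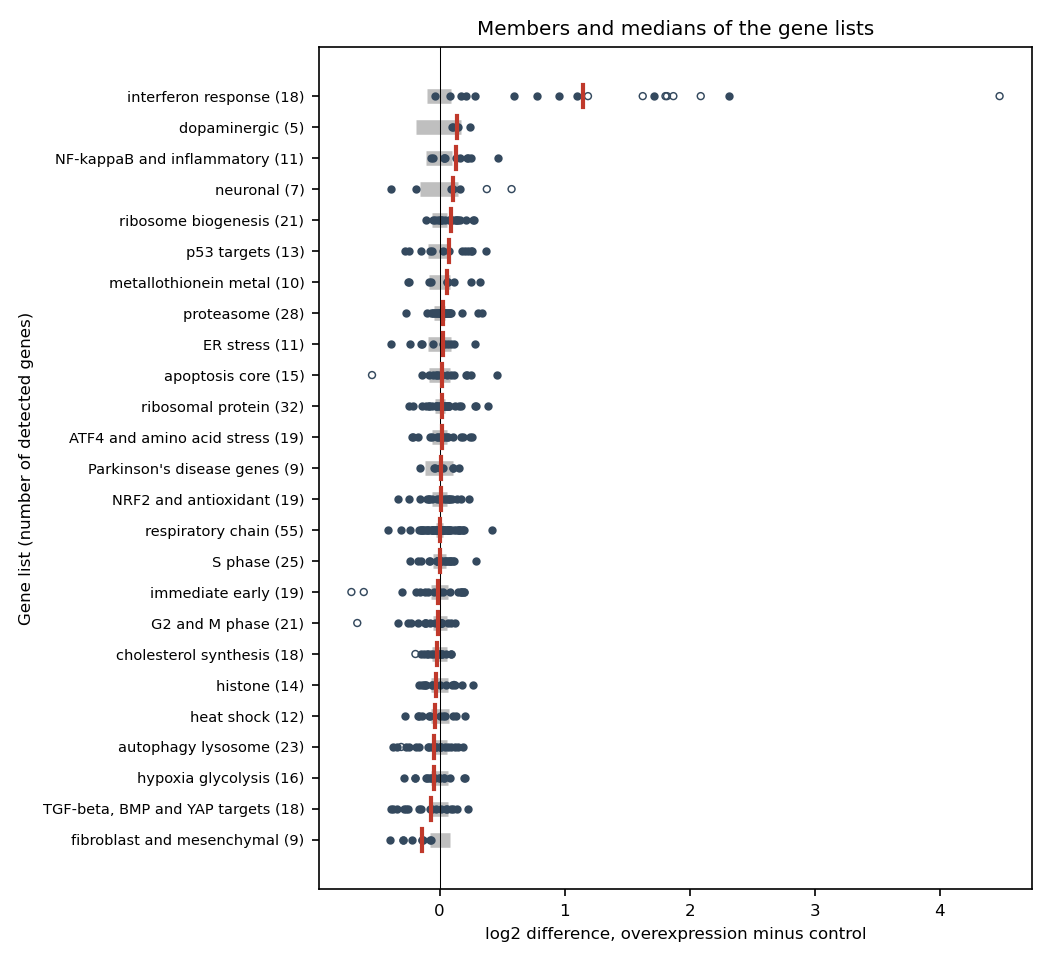
Log2 differences (overexpression minus control) of the detected members of the 25 gene lists with a percentile, with open circles for members detected on 1 array only, red lines at the list medians and grey bars for the central 95% of medians of matched random lists. The interferon median of 1.14 stands apart, and the fibroblast and mesenchymal median of -0.14 is the lowest.

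The few detected markers of dopamine neurons differed little. Of the 21 genes of the dopaminergic list, 6 had a named probe and 5 were detected. Named probes were only those with a detection p-value under 0.05 on at least 1 array. The other genes of the list may therefore have been undetected or without a probe, and these cases cannot be told apart. The same holds for the other marker lists below. All 5 detected dopaminergic genes had positive differences, with a median of 0.14. This median lay at percentile 95.37, inside the central 95% of matched random lists, and at percentile 97.56, outside it, with unmatched random lists. Control signals of Nr4a2 (274), Foxa2 (255) and Gch1 (288) were near the lowest detected signal of 201. Nr4a2, the transcription factor NURR1 needed for midbrain dopamine neurons, was at 0.24, Foxa2, a floor plate factor, at 0.10, and Qdpr and Gch1, genes of tetrahydrobiopterin metabolism, at 0.11 and 0.14. The probes of En1, the homeobox gene Engrailed-1, went in opposite directions at 0.15 and -0.17. Pan-neuronal markers had a median of 0.11 over 7 genes at percentile 93.32, with Syn1, a synaptic vesicle gene, at 0.17 and the adhesion molecule gene Ncam1 at -0.39. Stmn2, a regulator of microtubules, was at -0.19, and Uchl1, an abundant neuronal deubiquitinase, at 0.11. The highest fitted values of that list belonged to the neurofilament gene Nefm and the tubulin gene Tubb3, named after their values were seen, which were detected on the overexpression array only and had bounds of at least 1.28-fold and 1.07-fold higher. Of the 12 astrocyte markers, 3 were detected, with Gja1 (connexin 43) at 0.002 and Clu (clusterin) at 0.18. The other was Slc1a3, a glutamate transporter gene named after its value was seen, which was detected on the control array only and was at least 1.34-fold lower. The lists of oligodendrocyte, myeloid and endothelial markers had 1 detected gene each, Cnp at 0.26, Cd14 at 0.22 and Flt1 at 0.015. Genes of inherited Parkinson's disease had a median of 0.011 over 9 genes, with Fbxo7 at 0.16, Lrrk2 at -0.16 and Pink1 at -0.046.

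Genes of cellular stress and death had medians inside the central 95% of random lists. Antioxidant genes, mostly targets of NRF2, had a median of 0.010 over 19 genes at percentile 65.56, with the heme-degrading enzyme gene Hmox1 at 0.24 and the glutathione peroxidase gene Gpx1 at -0.33. Genes of autophagy and lysosomes had a median of -0.043 over 23 genes at percentile 8.10, with Bnip3l, a mitophagy receptor, at -0.38, the lysosomal channel gene Mcoln1 at -0.34, Atg4b at 0.18 and Atg16l1 at 0.15. Targets of p53 had a median of 0.076 over 13 genes at percentile 97.1, with the cell cycle inhibitor gene Cdkn1a at 0.37, Trp53inp1 at 0.26 and Phlda3 at -0.27. The median was 0.023 over 11 genes of the unfolded protein response, with the chaperone gene Hspa5 at -0.39 and Hyou1 at 0.28. It was 0.017 over 19 targets of ATF4 and amino acid stress, with Psat1 at 0.26 and Ddit3 at -0.22, and -0.037 over 12 heat shock chaperones, with Chordc1 at 0.20 and Hsp90aa1 at -0.28. It was 0.022 over 15 genes of the apoptosis machinery, with Bak1 at 0.46 and Casp8 at -0.14 among members detected on both arrays. Within this list the control signal of Bak1 (212) was near the lowest detected signal of 201. Apaf1, the caspase-activating scaffold, had that list's lowest fitted value, was detected on the control array only and was at least 1.02-fold lower (named after its value was seen).

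Growth and metabolic genes also lay inside the central 95%. Median differences were 0.001 over 25 genes of DNA replication, with Pcna at 0.29 and Dut at -0.24, and -0.014 over 21 genes of G2 and mitosis, with Birc5 at 0.12 and Ndc80 at -0.33. They were -0.030 over 14 histone genes, with H2ac22 at 0.26, and -0.011 over 19 immediate early genes, with Zfp36 at 0.20 and Junb at -0.30 among members detected on both arrays. The lowest fitted values in these lists belonged to Racgap1 of the mitosis list and to Egr2 and Fos of the immediate early list, named after their values were seen. These genes were detected on the control array only, and their bounds were at least 1.18-fold, 1.20-fold and 1.04-fold lower. Subunits of the respiratory chain had a median of 0.006 over 55 genes, with Ndufb7 at 0.42 and Atp5k at -0.41. Medians were -0.048 over 16 genes of glycolysis and hypoxia, with Pfkl at 0.21 and Vegfa at -0.20, and -0.022 over 18 genes of cholesterol synthesis, with Nsdhl at 0.092 and Mvd at -0.15. Cytosolic ribosomal proteins had a median of 0.022 over 32 genes, with Rps19 at 0.39 and Rps14 at -0.24, and proteasome subunits had 0.024 over 28 genes, with Psmc1 at 0.34 and Psmd12 at -0.27. Genes of metal response and iron handling had a median of 0.060 over 10 genes, with the transferrin receptor gene Tfrc at 0.32 and Slc39a10 at -0.26. Signs of medians this close to 0 depended on scaling, since median centring lowered the median of all genes to -0.10.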

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

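The test on neighbouring genes was chosen before its result was seen, and the other tests in this part were chosen only after the results they bear on were seen.

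Probes without a gene symbol took no part in the counts of genes, and 5 of them drew attention because they were detected on the overexpression array with a fitted difference of at least 2-fold above the control array. Probe ILMN_1229455 was detected on both arrays, at signals of 910 and 1954 and a log2 difference of 1.28. Probe ILMN_1256257 had a fitted difference of 3.04, but it was detected on the overexpression array only, and its bound was 2.42-fold. Another probe detected on both arrays had a log2 difference of 1.09. The remaining probes had fitted differences of 2.42 and 1.11, but they were not well above background on the control array, and their bounds were only 1.53-fold and 1.40-fold. In the other direction, probe ILMN_2519780 had signals of 1136 and 142.5, the latter not well above background, a ratio of 7.97, and was at least 9.20-fold lower on the background-corrected scale. The genes of these probes are not named here.

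The probes of Fbxw5, Pop4 and Tnfaip8 differed more between the arrays than those of the other named genes outside the interferon list. Background correction and normalization as the whole cause are argued against by the deposited signals themselves, whose smallest ratio among the 3 probes was 11.8. Activation of a chromosomal region reaching the neighbouring detected genes is argued against by the 5 nearest on each side, 30 genes in all. Their median log2 difference was -0.022 with a range of -0.49 to 0.52. They were taken by order along the chromosome with no limit on distance. Activation confined to a smaller stretch around each gene was therefore not tested. It stays open whether the probes may have read RNA other than the genes' own transcripts, such as the introduced construct or a cross-hybridizing transcript. These genes had 0 other named probes, and probe sequences were not used here. Only probes with a detection p-value under 0.05 on at least 1 array were named. Another probe of these genes that stayed at background on both arrays would therefore have been missed. A response of these genes to Oxi-beta stays open beside such a reading and was not tested.

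Interferon-induced genes were higher as a group on the overexpression array. Noise of signals near background is argued against by the members detected on both arrays, whose median of 0.593 lay above all 10000 matched random lists. Delivery of the construct in place of Oxi-beta itself could raise the same genes. Foreign nucleic acid in the cytosol is a known trigger of interferon. No array was labelled as cells given an empty construct, and whether the control cells received one is not given. On this basis the explanations cannot be told apart. A response to Oxi-beta therefore remains an untested alternative.

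Fibroblast and mesenchymal genes were slightly lower as a group. The list's percentile among matched random lists was at most 0.1 under each of 6 normalizations. A scaling shift shared by genes of like signal moves the list and its random lists together, so it would not place the list below them. These values argue against such a shift as the whole cause for the 9 genes. A shared shift cancels in the percentile, so its steadiness over the normalizations adds little. A scaling difference not shared by genes of like signal was not tested. Time or density in culture could give the same pattern. The overexpression array was labelled 12 h, with no untreated array at that time. Whether the control cells had spent fewer hours in culture is not given. Time or density in culture therefore cannot be told apart from an effect of Oxi-beta. The 9 genes are few, and markers of fibroblast identity such as Vim and Col1a1 are abundant in this line itself, at control signals of 44580 and 6298, so the pattern says little about another cell type (Col1a1 was named after its values were seen).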

How the results depend on the processing

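The alternative that puts genes detected on 1 array at their bounds was chosen only after the data were seen, and all others were planned. The 19 genes at least 2-fold higher became 8 with uncorrected signals floored at the lowest detected signal, 5 with detection required on both arrays and 39 at a 1.5-fold threshold. They numbered 14 to 21 under the other alternatives. The 1 gene at least 2-fold lower became 0 with the authors' values, with uncorrected floored signals, at offset 50, with detection on both arrays, at a 3-fold threshold and with bounds, 3 at detection 0.05 and with no filter, and 29 at 1.5-fold. Detection at 0.05 and no filter kept the same genes and are not separate checks. All genes counted higher with the authors' values (14), with uncorrected floored signals (8) and at offset 50 (16) were among the 19. The floor raises the control values of dim genes by construction, while 13 of the 19 had a ratio of deposited signals of 2 or more, and the cause of the other differences was not tested. The interferon median ranged from 0.463 with uncorrected floored signals to 1.15 with cyclic loess, above all random lists under each of the 6 normalizations. The median of ribosome assembly factors turned to -0.002 under median centring, where the median of all genes was -0.10, and relative to all genes it was 0.098, at percentile 99.9. The fibroblast and mesenchymal and NF-kappaB medians kept their sign under the 6 normalizations. Among the named genes 60 values moved beyond the spread between probes and 1131 did not, and En1 went from 0.15 to -0.01 when its probes were averaged. With unmatched random lists, members detected on both arrays or bounds, 2 list percentiles changed side, that of the dopaminergic list, 97.56 with unmatched random lists, and that of the TGF-beta, BMP and YAP list, 2.45 with bounds. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. Signal over background limits the dim genes, since 14 of the 19 higher genes were not well above background on the control array.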

Other observations

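The Reactome comparison was planned as an exploratory step, and the pathways and genes named from it were chosen only after their values were seen.

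Pathways of the extracellular matrix were among the lowest of the Reactome set. Of 612 pathways, 21 had medians below and 6 above the central 99% of matched random lists, where chance gives 3.1 on each side for independent pathways, and many pathways share genes. Extracellular matrix organization, with 97 detected genes, had a median log2 difference of -0.078, below all 10000 random lists. Elastic fibre formation had -0.17 over 18 genes, ECM proteoglycans -0.117 over 28 genes and collagen fibril assembly -0.141 over 19 genes. Among its matrix genes detected on both arrays, Emilin1 was at -0.55, Col6a1, a chain of collagen VI, at -0.30 with its other probe at -0.35, and Col5a1, a chain of collagen V, at -0.22. Col8a2 and Adamts4, a protease of matrix proteoglycans, were at least 1.5-fold lower by fitted value, but they were detected on the control array only, and their bounds were 1.36-fold and 1.08-fold. The laminin chain gene Lamb1 was among the highest members of the large pathway. The 7 pathways farthest below their random lists, in SDs of the random medians, were of the extracellular matrix, collagen or elastic fibres, and most of the other 14 were not. These included Platelet degranulation (-0.075 over 35 genes), Hemostasis (-0.036 over 154 genes), Developmental Biology (-0.039 over 168 genes), Axon guidance (-0.039 over 120 genes), Signaling by NOTCH1 (-0.096 over 27 genes), Mitochondrial Fatty Acid Beta-Oxidation (-0.164 over 11 genes) and Calmodulin induced events (-0.128 over 13 genes).

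At the upper end lay pathways that share genes of the nuclear pore. Nuclear Envelope Breakdown had a median of 0.084 over 30 genes at percentile 99.86, and its highest members included Nup54, Seh1l, Nup93 and Nup210, components of the pore. Hexose transport, which had the same 4 genes among its highest members, had 0.092 over 24 genes at percentile 99.74. Interferon Signaling had 0.057 over 45 genes at percentile 99.38, just inside the central 99%. Interferon gamma signaling had 0.064 over 30 genes at percentile 99.07, also inside. Antiviral mechanism by IFN-stimulated genes had only 0.017 over 13 genes at percentile 68.28.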
